A study of Arabidopsis thaliana with 4 samples.

How the data were processed

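Total RNA from Arabidopsis thaliana leaf primordia was measured on Affymetrix expression arrays, 2 for wild type and 2 for the mutant an3-4, with both genotypes given the ecotype Col-0 in the labels. Per the labels' protocols, plants grew at 22 °C under continuous light, the first set of leaf primordia was frozen in liquid nitrogen 7 days after sowing, RNA was prepared with a spin-column kit, and biotinylated cRNA was made from 10 µg of total RNA. The deposited values are 1 signal intensity per probe set on a linear scale, for 22810 probe sets of which 64 are controls. Per the submitters' processing notes the authors used MAS5, a method that subtracts background and mismatch signal and scales each array to a target mean. Its version and target were not given in the sources used here.

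The deposited signals were checked for their scale. With 2% of values trimmed from each end, the mean signal was 143 on both arrays numbered 1 and 169 on both arrays numbered 2, a log2 ratio of 0.24. Each same-numbered pair therefore sat on its own scale. Because each pair holds 1 array of each genotype, this offset leaves the fold change between genotypes as it is but adds to the spread within each genotype. The median residual SD was 0.20 on the log2 scale as deposited and 0.11 after all arrays were brought to 1 trimmed mean. Array medians differed by at most 0.30 on the log2 scale, below the limit of 0.5 set for centring, so the reported results use the values as deposited.

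Signals were tested on the log2 scale without an offset in limma 3.58.1 under R 4.3.3, with lmFit, eBayes with an intensity trend, and genotype as the only term. Control probe sets and the 40% of probe sets with the lowest mean log2 signal were left out, which left 13647. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05. The arrays leave 2 residual degrees of freedom. limma estimated infinite prior degrees of freedom for the deposited values, so each probe set's spread came from the trend over all probe sets alone, and 11.1 for the arrays at 1 trimmed mean. Array data carry no counting depth, and the number of arrays limits the precision. Signal values are given as mean ± SD (n = 2 arrays) and log2 fold changes of an3-4 over wild type as estimate ± SE. No detection calls were used. Where both signals of a group lay under the 40th percentile of all probe sets on their arrays, the change with every signal raised at least to that percentile is given as a bound, a step chosen after the data were examined.

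Probe sets were named from the platform annotation given, with symbols updated through gene identifiers to the RefSeq gene table of assembly TAIR10.1. One gene was listed for 13513 probe sets, several genes for 503, and none for 8730 probe sets that are not controls. Of the probe sets with 1 gene, 13436 matched the RefSeq table. That table was used for names and for the order of genes along chromosomes, and no coordinates were taken from it. A gene was represented by its probe set with the highest mean log2 signal, which gave 7328 named genes past the filter.

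Genes to be named were fixed before the data were examined. They were the 15 genes higher and the 15 genes lower with the largest log2 fold change among called genes whose signals did not overlap between genotypes, and from each gene list the called members, up to 4, or else the 2 members with the smallest p. The 23 gene lists, with 347 genes, were fixed at the same time. The annotation named 53 of these genes, and 42 passed the filter. Lists with at least 3 members past the filter were tested with camera at a preset correlation of 0.01, with an estimated correlation beside it, and with fry. Because few listed genes were named, families read from gene symbols, with at least 5 genes each, and the genes of both organelle genomes were added as further sets before any fold change was looked at. Unnamed probe sets are given by identifier.

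Neighbours of the mutated locus were the 20 nearest measured genes on each side, without the signal filter, compared with the other genes of the chromosome by a two-sided permutation test with 100000 resamples. The order of calls along chromosomes was tested with 10000 permutations over named genes past the filter, by counting calls that have another call of the same direction within 10 positions. That search was chosen after the data were examined.

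Alternatives were quantile normalization, median centring, no filter, a filter of 60%, an offset of 32, eBayes without the trend, robust eBayes, the replicate number as a block, leaving out each array, an adjusted p under 0.1, a rule without a test that needs every an3-4 array at least 2-fold above, or below, every wild-type array, and other ways to pick probe sets for the lists. A single trimmed mean for all 4 arrays, with and without the block, was added after the data were examined.

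The scripts were tested on simulated data drawn from the real means and spread, over 13647 probe sets with 200 changed, in 20 runs. With the offset between pairs kept, 1.3% of probe sets changed by 0.5 on the log2 scale were called, 78.3% of those changed by 1, and 99.9% of those changed by 2, and 1.31% of calls were false. On 1 scale 41.1% of probe sets changed by 0.5 were called, and 4.14% of calls were false. Of 200 random lists of 5 genes with no change, camera with the preset correlation gave 3% a p under 0.05. These genes were simulated independently and without the offset between pairs, so the 3% does not cover lists of correlated genes. In the data the estimated correlation was 0.18 for the flavonoid and anthocyanin list and 0.60 for the mitochondrion-encoded genes. It was estimated on the deposited values with 2 residual degrees of freedom, so the offset shared by each same-numbered pair enters it. For families read from symbols it ran from -0.14 (SWEET) to 0.94 (ALDH). Tests with an estimated correlation, and fry, therefore cannot separate correlation within a list from that offset.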

Results

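The data are 4 arrays of Arabidopsis leaf primordia harvested 7 days after sowing, 2 from wild type and 2 from the mutant an3-4. ANGUSTIFOLIA3, also called GIF1, is a transcriptional coactivator that promotes cell proliferation in young leaves, and its mutants form narrow leaves. The study asked which transcripts differ between mutant and wild type at this stage. Median signals were 61.7 and 70.8 on the wild-type arrays and 61.8 and 75.8 on the an3-4 arrays. Over the 13647 probe sets tested, log2 signals correlated at 0.988 between the wild-type arrays, at 0.989 between the an3-4 arrays and at 0.968 to 0.969 across genotypes. These correlations run across probe sets, which are not independent replicates. The labels call the arrays of a genotype replicates and do not say that they came from separate cultures. The p-values therefore measure a spread between these arrays, which may be technical. As deposited, that spread is pooled over probe sets and includes the offset between pairs, so the smallest p-values depend on the scale. AT4G19240 had a limma adjusted p of 2.34e-28 as deposited and of 1.07e-07 at 1 trimmed mean. An exact permutation test of 2 arrays against 2 cannot give a p below 0.333, so all calls rest on limma's spread over all probe sets.

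The level of AN3 itself, of its relatives GIF2 and GIF3 and of the GROWTH-REGULATING FACTOR genes was not analysed here, because the annotation used names no probe set for them. The genotype labels were therefore not checked against the mutated gene.

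Between the genotypes, 197 probe sets were higher and 196 were lower in an3-4. All 3 measured genes of the 13 on the flavonoid and anthocyanin list fell, DFR most, and as a set the list had an adjusted p of 0.0902 with an estimated correlation. The clock gene GI and the organelle genes cox1, ccb452 and rps4 rose. Of the 393 called probe sets, 249 changed by at least 1 on the log2 scale, 212 carried 1 gene name, 17 carried several and 164 carried none. Counted by gene, 97 of the 7328 named genes were higher and 113 were lower. The count depended on how the arrays were scaled. The deposited scale differed between same-numbered pairs. limma called 1685 probe sets (896 higher, 789 lower) with all arrays at 1 trimmed mean and, at either scale, 2154 (1170 higher, 984 lower) with the pair as a block, and these kept 388 and 392 of the 393. Leaving out 1 array gave fewer calls: 126 without wild-type replicate 1, 139 without wild-type replicate 2, 211 without an3-4 replicate 1 and 201 without an3-4 replicate 2. The median log2 fold change of all tested probe sets was 0.02.

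**Figure D1:**
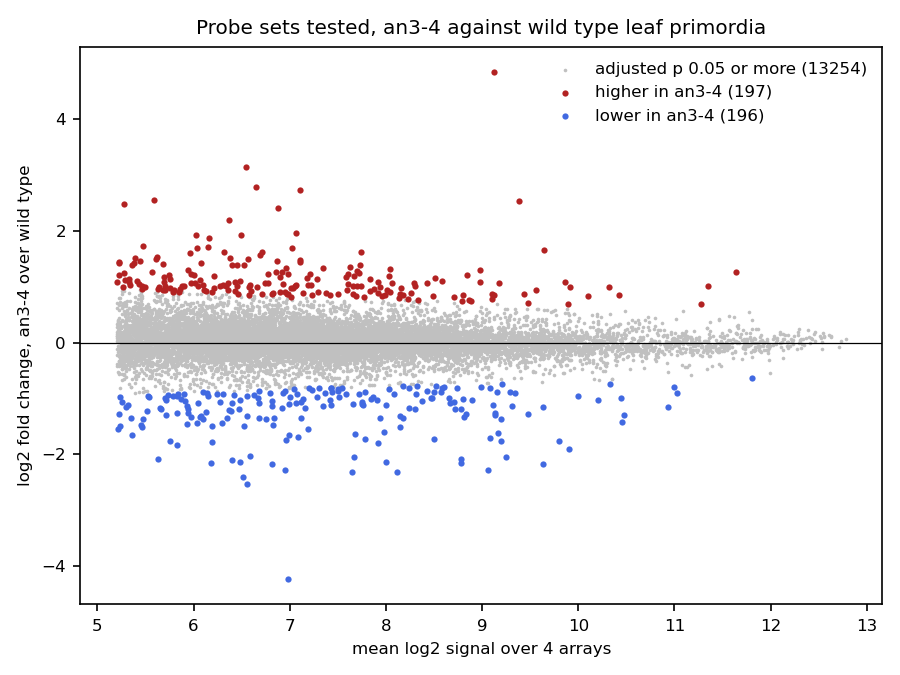
Log2 fold change of an3-4 over wild type (vertical axis) against the mean log2 signal of the 4 arrays (horizontal axis) for the 13647 probe sets tested. Red points are the 197 probe sets higher in an3-4 and blue points the 196 lower at an adjusted p under 0.05 in limma, and gray points are the others.

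Among named genes, AT4G19240 rose most, from a signal of 32.1 ± 9.93 in wild type to 277 ± 5.55 in an3-4 (SD, n = 2), a log2 fold change of 3.15 ± 0.27 (limma adjusted p = 2.34e-28). Of its wild-type signals 1 lay under the 40th percentile of its array, and with that signal raised to the percentile the change was 2.91, still the largest. AT5G15360 rose by 2.74 ± 0.26, from 53.7 ± 4.65 to 367 ± 124. AT1G62770 followed at 2.2, AT5G62360 at 1.95, AT5G19100 at 1.93 and AT1G12080 at 1.88. The other members of the 15 genes with the largest rises were AT1G08230, AT2G40960, AT3G11930, GI, AT2G43535, AT1G78450, AT1G50290, AT4G14020 and AT3G62550, from 1.69 down to 1.49. AT1G78450 lost its call when wild-type replicate 2 was left out of the limma fit (log2 fold change 1.33). AT4G14020 lost its call when wild-type replicate 1 was left out (1.23). Both wild-type signals of these 2 genes lay under the 40th percentile of their arrays, and raised to it they leave a rise of at least 1.2 for AT1G78450 and 0.96 for AT4G14020. Of the probe sets without a listed gene, 263174_at rose most, from 128 ± 104 to 2985 ± 188, a log2 fold change of 4.84, and 261226_at rose by 2.79.

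The largest decline of a named gene was that of AT3G44430, from 229 ± 49.2 to 39.9 ± 11.5, a log2 fold change of -2.53 ± 0.27 (limma adjusted p = 2.80e-18). AT5G62210 had a log2 fold change of -2.41, AT4G02850 of -2.32 and AT1G23960 of -2.27. ZW9 fell from 1178 ± 63.0 to 241 ± 14.0 and ECS1 from 1854 ± 97.7 to 498 ± 95.7, log2 fold changes of -2.29 and -1.91. MSRB5, a methionine sulfoxide reductase gene, had a signal of 24.5 ± 6.44 in an3-4, under the 40th percentile on both arrays, so its log2 fold change of -2.08 has -1.43 as its bound. The remaining genes among the 15 were DFR, AT1G65370, AT1G35612, AT1G33790, AT1G52100, AT4G02540, AT3G19520 and AT1G11280, from -2.16 to -1.74. AT3G44430, AT4G02850, AT1G65370 and AT4G02540 of these, and AT1G62770 of the genes that rose, lie in the stretches of chromosomes 1, 3 and 4 that hold many lower calls. Of probe sets without a listed gene, 246103_at fell from 551 ± 96.9 to 29.3 ± 0.15, under the 40th percentile on both an3-4 arrays, so its log2 fold change of -4.22 has -3.85 as its bound, and 255257_at had -2.17.

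**Figure D2:**
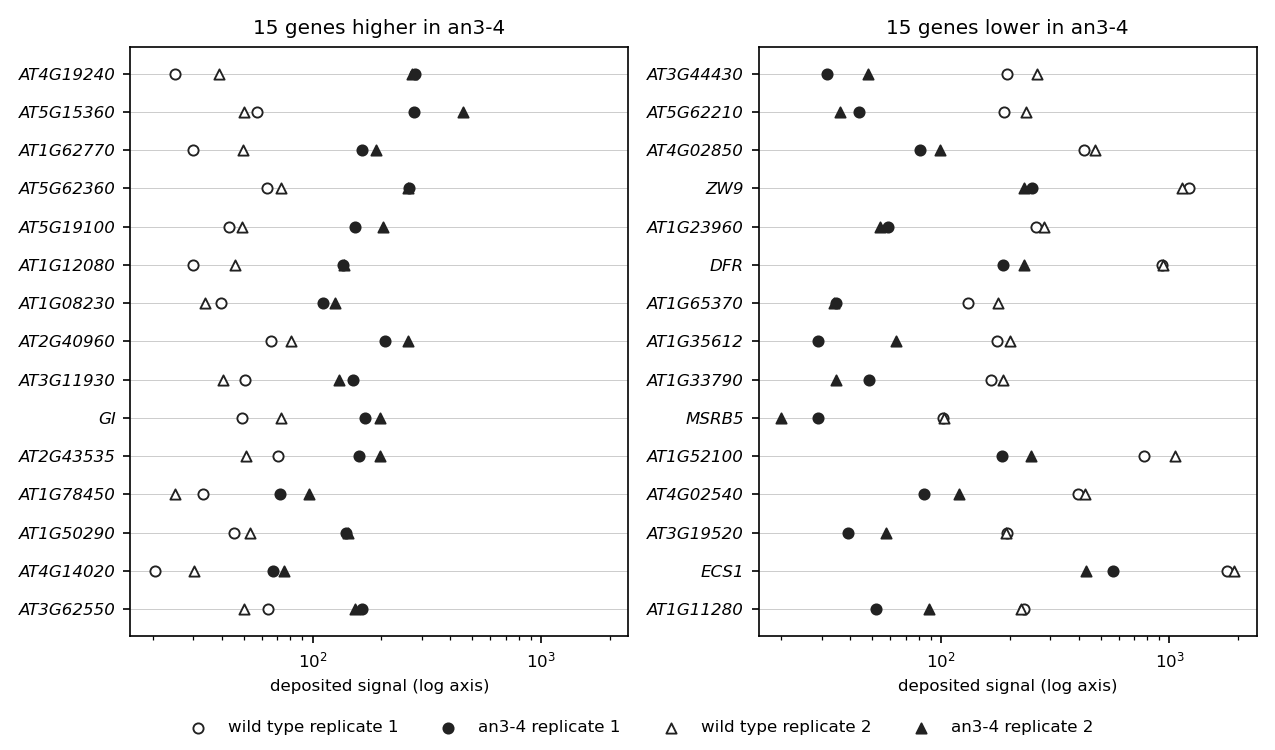
Deposited signal per array (log axis) of the 15 genes higher and the 15 genes lower in an3-4 with the largest log2 fold changes. Open symbols are wild type and filled symbols an3-4, circles replicate 1 and triangles replicate 2, and the genotypes do not overlap for any gene shown, which is part of how the genes were chosen.

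All 3 measured genes of the flavonoid and anthocyanin list fell. DFR, dihydroflavonol 4-reductase, fell from 931 ± 10.3 to 209 ± 30.6, a log2 fold change of -2.16 ± 0.23 (limma adjusted p = 1.60e-17). UF3GT (AT5G54060) and AT4G14090, both glycosyltransferase genes of anthocyanin modification, had log2 fold changes of -1.73 ± 0.25 and -1.36 ± 0.24. Adjusted over the list alone, the same count of 3 was lower. The list had a median log2 fold change of -1.73 with an adjusted p of 1.02e-22 in camera with the preset correlation, the only call among the 7 lists tested. With an estimated correlation the adjusted p was 0.0902, and fry gave an adjusted p of 0.0273. Both were run on the deposited values, where the offset between pairs enters the estimated correlation and the spread that fry uses. The list holds 13 genes, so 10 of them, chalcone synthase among them, were not analysed here.

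Cell division genes were sparsely covered. The Aurora kinase genes AUR1, AUR2 and AUR3, the 3 measured members of the mitotic list, had log2 fold changes of -0.18, -0.27 and -0.54 ± 0.26, and none was called in limma, over all genes or adjusted over the list alone. AUR3 was below an unadjusted p of 0.05. The list had an adjusted p of 0.204 in camera and of 0.845 with an estimated correlation. In the DNA replication list, PRL, the MCM7 helicase subunit, had -0.53 ± 0.23 (limma adjusted p = 0.345) and lies in the chromosome 4 stretch with many lower calls, and ICU2 had 0.01. Adjusted over the list alone, PRL was lower. With all arrays at 1 trimmed mean, AUR3 (adjusted p = 0.0314) and PRL (adjusted p = 0.00571) passed in limma. SIM and AT1G08180, from the list of CDK inhibitors, had 0.01 and -0.12 and were not called.

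Among the leaf growth regulators 1 of 4 measured genes rose. ARL, an ARGOS relative that promotes organ growth, rose from 89.1 ± 25.5 to 163 ± 7.80, a log2 fold change of 0.91 ± 0.26 (limma adjusted p = 0.0218). It lost the call when any 1 array was left out, in fits that leave a genotype with 1 array and 1 scale. The log2 fold change of ARL was then 1.2 without wild-type replicate 2 and 0.61 without wild-type replicate 1. Without an3-4 replicates 1 and 2 it was 0.95 and 0.86. With all arrays at 1 trimmed mean ARL passed in limma (adjusted p = 9.93e-04). JAG (-0.57), SPT (0.37) and NUB (0.08) were not called. Adjusted over the list alone, ARL was also the only call, and the list as a set had an adjusted p of 0.394 in camera and 0.845 with an estimated correlation. Of the leaf-side identity lists, PHV (0.12) for the adaxial side and YAB5 (0.11) and YAB3 (-0.06) for the abaxial side were not called. The stomatal regulators SPCH (-0.31) and FMA (0.01) were not called, and none of these 5 genes had an unadjusted p under 0.05.

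ARR15, a cytokinin-induced type-A response regulator and the only measured member of the cytokinin list, fell from 81.7 ± 2.90 to 34.5 ± 11.6, a log2 fold change of -1.29 ± 0.29 (limma adjusted p = 6.20e-04). Its call was lost without wild-type replicate 1 (-1.25), wild-type replicate 2 (-1.32) or an3-4 replicate 2 (-0.94). With all arrays at 1 trimmed mean ARR15 passed in limma (adjusted p = 0.00668). Of its an3-4 signals 1 lay under the 40th percentile of its array, and with that signal raised to the percentile the change was -0.94. The auxin-response genes WES1 (GH3.5, 0.59 ± 0.23), IAA29 (0.66 ± 0.29) and GH3.3 (-0.26 ± 0.24) were not called over all genes. Adjusted over the list alone, WES1 and IAA29 were higher, and both passed in limma at 1 trimmed mean (adjusted p = 3.73e-04 and 0.0370). The auxin list had an adjusted p of 0.257 in camera and 0.845 with an estimated correlation. Of the expansin and XTH genes, which act on the cell wall, EXPA8 (0.58 ± 0.22), XTH16 (0.36 ± 0.23), EXPA4 (-0.15) and EXPA15 (-0.15) were not called. EXPA8 was higher adjusted over the list alone, and EXPA8 and XTH16 passed in limma at 1 trimmed mean (adjusted p = 3.60e-04 and 0.0178). That list had an adjusted p of 0.394 in camera and 0.845 with an estimated correlation.

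GI, which encodes the clock protein GIGANTEA, rose from 60.8 ± 16.7 to 183 ± 19.5, a log2 fold change of 1.62 ± 0.26 (limma adjusted p = 2.08e-07). It was the only measured gene of the 10 on the clock list. STZ, a zinc finger gene from the list of wounding and stress, had 0.16 and was not called.

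None of the 7 photosynthesis genes and none of the 6 cytosolic ribosomal protein genes was called in limma, over all genes, adjusted over the list alone or at an unadjusted p under 0.05. Their median log2 fold changes were 0.07 and -0.06, with adjusted p of 0.966 and 0.394 in camera and of 0.987 and 0.845 with an estimated correlation. The largest difference among the photosynthesis genes was -0.39 ± 0.20 for LHCB4.2, which passed in limma at 1 trimmed mean (adjusted p = 0.0198), and PSAE-1 had 0.20 ± 0.19. Among ribosomal protein genes AT2G19730 and AT5G27700 both had -0.18 ± 0.20. The lists for meristem and boundary, root, trichome, vascular tissue, seed storage, CIN-type TCP genes, GIF genes and GRF genes had no named member past the filter and were not analysed here.

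**Figure D3:**
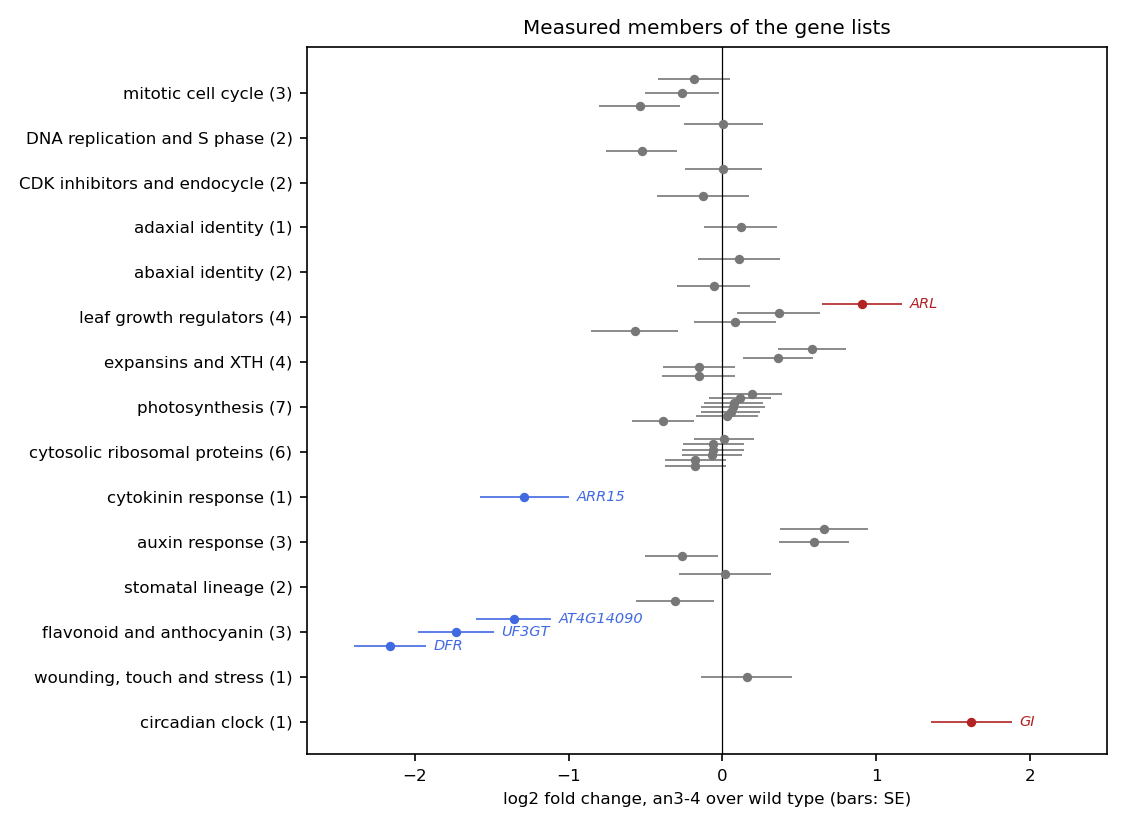
Log2 fold change of an3-4 over wild type (horizontal axis, bars SE) for the 42 measured members of the gene lists, with the number of members per list in brackets. Red marks members higher and blue members lower at an adjusted p under 0.05 in limma, and the 3 flavonoid and anthocyanin genes lie furthest to the left.

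Of the 31 symbol families and organelle sets tested, only the mitochondrion-encoded genes passed in camera with the preset correlation. Their 9 genes had a median log2 fold change of 0.62 (adjusted p = 1.68e-05), and the adjusted p was 0.998 with an estimated correlation and 0.654 in fry. At 1 trimmed mean with the preset correlation the adjusted p in camera was 4.92e-04. Of the 9, cox1, a subunit of cytochrome c oxidase, rose by 1.22 ± 0.26 (limma adjusted p = 3.06e-04) and ccb452, which acts in cytochrome c maturation, rose by 1.07 ± 0.26. The other 7 were not called, though a dimmer probe set of nad1 than the one used was, at 1.43 against 0.24. The 69 plastid-encoded genes had a median of 0.13 and an adjusted p of 0.0521 in camera, 0.998 with an estimated correlation, and 7.32e-04 at 1 trimmed mean with the preset correlation. Of the plastid-encoded genes only rps4, a ribosomal protein gene, was called, with signals of 2081 and 4955 and a log2 fold change of 1.26 ± 0.20 (limma adjusted p = 7.05e-08). The TUB and TET families, with 1 called member each, TUB1 and, in the chromosome 3 stretch with many lower calls, TET3, also had an adjusted p of 0.0521 in camera, and 0.0201 and 0.0454 at 1 trimmed mean. With an estimated correlation the adjusted p was 0.998 for both. Control probe sets for the 3' and 5' ends of actin, GAPDH and ubiquitin transcripts, a measure of RNA integrity, had 3' to 5' log2 ratios that lay higher on both an3-4 arrays than on both wild-type arrays for 3 of 6 pairs. Their mean differences were 0.23, 0.14 and 0.12, and the other 3 pairs overlapped between the genotypes, with differences of 0.19, 0.16 and -0.02.

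Around the AN3 locus, the 40 nearest measured genes had a mean log2 fold change of -0.08 against 0.03 for the other 2942 measured genes of chromosome 5. The difference of -0.11 did not pass (two-sided permutation test, p = 0.262), and 4 of the 40 genes passed the signal filter. The others, too dim for the filter, had log2 fold changes from -3.57 to 3.39, so the test cannot exclude lower neighbours. AT5G28500, 1 of the 4 past the filter, fell, with a log2 fold change of -1.71 ± 0.23 (limma adjusted p = 2.84e-11), and was singled out after its values were seen. With an offset of 32 added to each signal the difference was -0.0773 with a permutation p of 0.0304.

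Lower calls were unevenly spread over the genome. Chromosome 2 held 1 of the 113 lower genes among 1037 tested, against 49 of 1886 on chromosome 1, 21 of 1507 on chromosome 3, 22 of 1057 on chromosome 4 and 20 of 1748 on chromosome 5 (one-sided permutation test over chromosomes, p = 1e-04, the smallest that 10000 permutations can give). For higher calls, 12 of them on chromosome 2, the same permutation test gave p = 0.873. Of the lower genes, 65 had another within 10 positions in gene order against 30.3 by chance (one-sided permutation p = 1e-04), and of 93 higher genes on these chromosomes 34 did against 20.9 (permutation p = 0.0111). At 1 trimmed mean 297 of 386 lower genes did against 256 (permutation p = 1e-04), and 295 of 420 higher genes against 292 (permutation p = 0.401). Divided into 147 consecutive groups of up to 50 genes, 5 groups held at least 5 lower genes each. These ran from AT1G61670 to AT1G63420, AT1G63430 to AT1G65010 and AT1G65020 to AT1G67330, which adjoin, and from AT3G44100 to AT3G47000 and AT4G01897 to AT4G03340. In them 11.6% of 250 genes were lower and 2.8% higher, against 1.2% and 1.23% of the other genes. The stretches were chosen for their many lower genes, so the larger share of lower genes in them follows from that choice. Without these stretches 84 genes were lower and 86 higher, and the same choice reduces the count of lower genes.

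**Figure D4:**
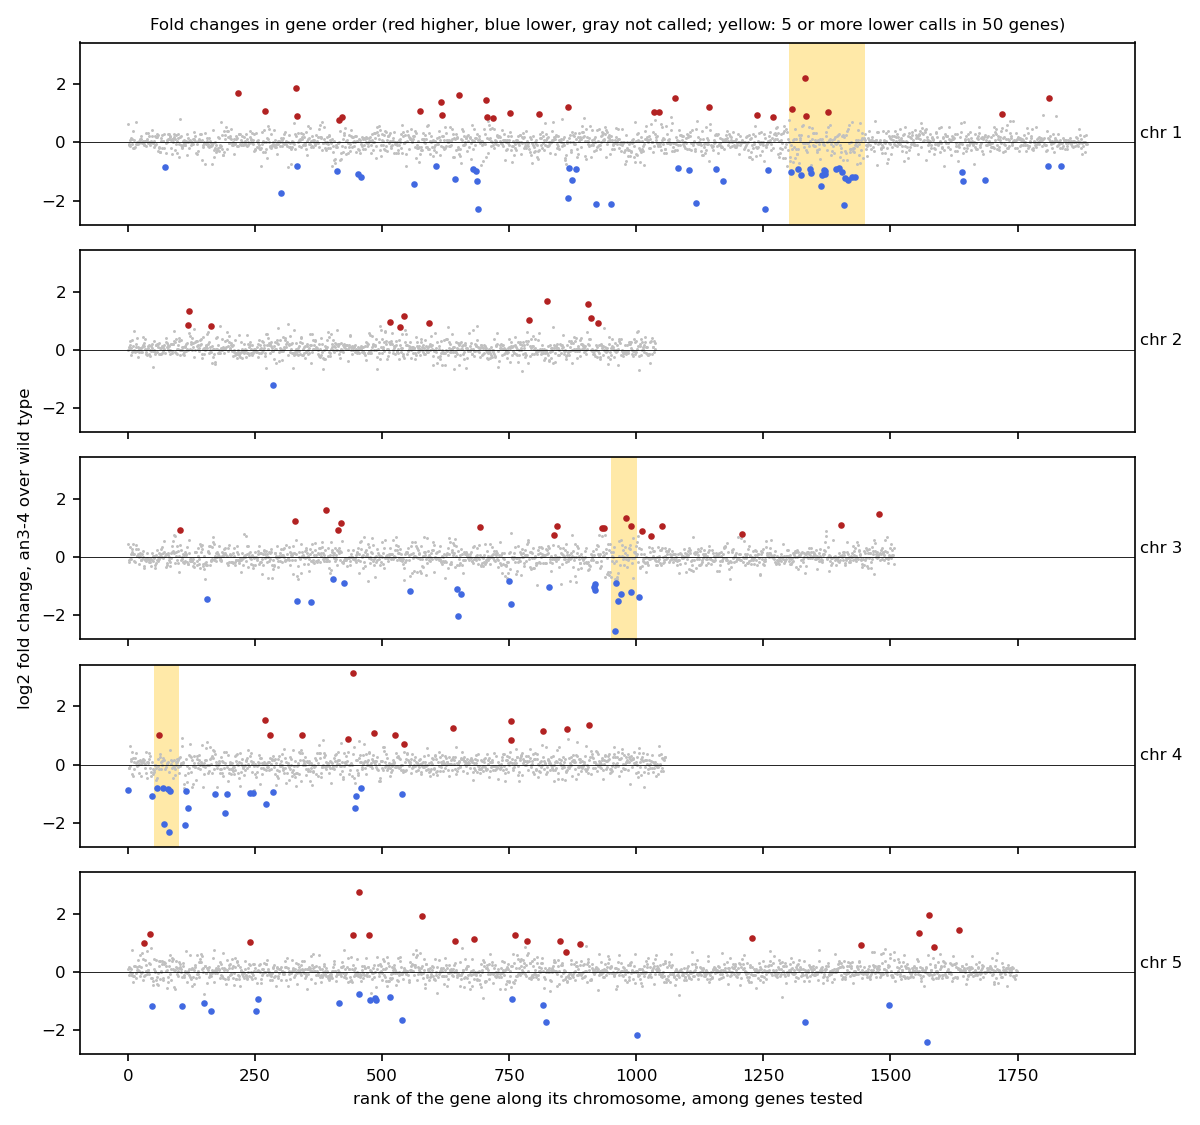
Log2 fold change of an3-4 over wild type (vertical axis) for each named gene tested, by its rank along chromosomes 1 to 5 (horizontal axis). Red points were called higher, blue points lower and gray points were not called, and yellow bands mark the 5 stretches of 50 genes with at least 5 lower genes.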

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

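The single trimmed mean for all arrays, with and without the block, was chosen after the data were examined, and the other settings before. No called probe set changed direction in any setting in which it was tested. The counts of higher and lower probe sets, 197 and 196, became 866 and 849 with quantile normalization, 730 and 974 with median centring, 896 and 789 at 1 trimmed mean, and 1170 and 984 with the replicate block, at either scale. They fell to 103 and 117 with the 60% filter, which tests 9098 probe sets, and 53 and 75 probe sets met the rule without a test that every an3-4 array differ at least 2-fold the same way from every wild-type array. Leaving out 1 array gave 35 to 128 higher and 57 to 131 lower, with the lone array assumed to vary like the other genotype. These fits moved the median log2 fold change to between -0.11 and 0.15, since a genotype then holds 1 scale only. Without a filter, with the offset of 32, without the trend, with robust eBayes or at an adjusted p under 0.1, counts stayed within 1.5 times. Arrays with the same replicate number share a deposited scale, and the labels name no shared batch. At 1 trimmed mean the differences between replicates correlated at 0.04 between the genotypes, yet the block still raised the count there, and a shared batch stays open. The block changed no call of a gene list.

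The flavonoid and anthocyanin list (-1.73) missed the threshold only with an estimated correlation (adjusted p = 0.0902, against at most 2.13e-09 in every setting run with the preset one). On the deposited values that estimate takes in the offset between pairs. The difference for the neighbours of AN3 passed, of the settings run for it, only with the offset of 32 (-0.0773), and the cause was not tested. Of 731 combinations of the 54 named genes with a setting, 685 kept their direction and side of the threshold, 37 gained a call, 9 lost one and 0 reversed. All 9 losses came from leaving out an array and concern ARL, ARR15, AT1G78450 and AT4G14020. The gains concern AUR3, EXPA8, IAA29, LHCB4.2, PRL, PSAE-1, WES1 and XTH16, each with the block or another scale. Probe sets in the dimmest 40% were left out, so changes confined to weakly expressed genes were not assessed.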

Other observations

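The genes named in the next paragraph, the single trimmed mean for all arrays, the search along chromosomes and the test of the control pairs were chosen after the data were examined. The test for deletions replaced an earlier one after the result of that one was seen.

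Single genes outside the fixed lists that limma called, with no set test of a shared pathway, included the following. AT5MAT, an anthocyanin malonyltransferase gene, had a log2 fold change of -1.14 ± 0.26, CHIL, a chalcone isomerase-like protein gene, -1.07 ± 0.23, and BCAT4, which acts in the synthesis of methionine-derived glucosinolates, -1.27 ± 0.22. How many other genes of these pathways were measured was not counted. MSRB6, the neighbour of MSRB5, had -0.90 ± 0.26, COR47, a cold-induced dehydrin gene, rose by 1.07, and EXLA1, in the chromosome 3 stretch, rose by 1.08 ± 0.27. Of the 5 GSTU glutathione transferase genes, GSTU16 (-0.95) and GSTU20 (-0.80) fell and 3 were not called. The GSTU family had a median of 0.12 but a mean of -0.22, with an adjusted p of 0.280 in camera and 0.998 with an estimated correlation. Of 5 EXPA expansin genes 1 fell, EXPA9 at -1.15 ± 0.30. Its signals in an3-4 lay under the 40th percentile on both arrays, so this change has -0.62 as its bound. The EXPA family had an adjusted p of 0.253 in camera and 0.998 with an estimated correlation. The tubulin gene TUB1 rose by 0.97 ± 0.24, and the 5 tubulin genes tested, of which the other 4 were not called, had a median of 0.38 with an adjusted p of 0.0521 in camera, 0.0201 at 1 trimmed mean and 0.998 with an estimated correlation.

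The number of calls depended on the deposited scale, on which each same-numbered pair has its own mean. Had that scaling held the count down, bringing all arrays to 1 trimmed mean would have raised it over 1.5 times, and it rose from 393 to 1685, while the median residual SD went from 0.20 to 0.11. A rise was largely fixed in advance, because the offset adds to the spread within each genotype and leaves fold changes as they are. The reported count is the lower one of these, and which is nearer to the number of true differences was not tested. The simulated data recovered 1.3% of log2 changes of 0.5 with the offset kept and 41.1% without it. That offset was put into them by design, so they are no separate evidence. Whether the arrays of a genotype stand for separate cultures stays open at either scale.

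Lower genes gathered in stretches of chromosomes 1, 3 and 4. Isolated tandem groups with lower genes at most 5 positions apart would leave no gathering once each group is counted once. Yet 50 of 81 remaining genes had another within 30 positions against 35.7 by chance (permutation p = 0.0033). Positions are ranks among the named genes tested, and family membership was not examined. Families with wider gaps, or with several groups near each other, therefore stay open. One contiguous deletion per stretch would lower most measured genes between the first and the last lower gene, and at most 23.1% of them were lower in any of the 5 stretches, which leaves smaller separate deletions open. Sequence variants or a segment from another line in the mutant, which could weaken hybridization, stay open: in stretches found on odd-numbered genes, the share of even-numbered genes that were lower was 6.35 times that elsewhere (8% against 1.26%, Fisher's exact p = 1.12e-05), but lower against higher calls there, 10 to 3, were not shown to differ from 44 to 35 elsewhere (Fisher's exact p = 0.225). With a single mutant line and no sequence of it used here, such variants cannot be told apart from genes regulated together in these stretches.

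The mitochondrion-encoded genes were higher in an3-4 as a set with the preset correlation only. RNA integrity differing between groups could shift such transcripts, and 3 of the 6 control pairs had higher 3' to 5' ratios on both an3-4 arrays while 3 overlapped. With 2 arrays each this neither shows nor excludes such a difference, so it cannot be told apart from an effect of the genotype.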
